A study of Mus musculus with 4 samples.

How the data were processed

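Accessible chromatin was profiled by ATAC-seq, in which the Tn5 transposase cuts open DNA and inserts sequencing adaptors, in livers of female mice aged 11 weeks on the FVB background. The libraries came from frozen liver taken through the Omni-ATAC procedure, per the labels' protocols. There were 4 libraries, 2 of wild-type mice (WT) and 2 of mice labelled PA. The labels describe the mutant mice as carrying a hypomorphic form of Pcca, the gene of the alpha subunit of propionyl-CoA carboxylase, whose loss causes propionic acidemia. The series design calls the replicates biological. Group and replicate number were taken from each sample's title.

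For each library the authors deposited one list of peak positions, with chromosome, start and end, so the values used here are positions and carry no measurement unit. Per the submitters' processing notes, the tools were cutadapt 3.5, Bowtie2 2.5.1, SAMtools 1.17, R 4.1.2, HOMER 4.10 and bedtools 2.31.0, and the genome build was GRCm38 (mm10). The peak caller, its threshold, the read filters and any shift of read ends for the transposase are not given in the sources used here. Nearly all peaks were 400 bp long, with 3 or 4 exceptions per list. Such a list records whether a window passed the caller's threshold in a library, and not how open it was. A library with more reads, or with a lower background, can pass the threshold at more places. Read depth is unknown, so no interval that needs it is given, and intervals on shares of regions cover the counting of regions only.

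Lines of the lists were not in genome order. Over regions shared by a pair of libraries, place in the file was correlated between the libraries, with Spearman's rho from 0.862 to 0.929 across regions, which are not independent replicates. What the authors ordered the lines by is not given in the sources used here. Place in the file was therefore used only for alternatives and for a description of where in its own list a peak stands, and these uses were chosen after seeing the data.

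Peaks of the 4 libraries were merged where they overlapped or touched, and a region was called in a library when at least 1 bp of a peak of that library lay in it. A PA-only region was called in both PA libraries and in neither WT library, and a WT-only region in both WT libraries and in neither PA library. The same counts were made for the other splits of the libraries into pairs (WT 1 with PA 1 against WT 2 with PA 2, and WT 1 with PA 2 against WT 2 with PA 1). There are 3 such splits, so the smallest p an exact permutation of the libraries can give is 0.333, and values per library are given without a test. Pairs of libraries were compared by the base-pair Jaccard index, the length shared divided by the length covered by either. The products of the counts on each side of a split were compared as ratios, with 95% intervals from Poisson counting error on the log scale. Shares of regions have exact Clopper-Pearson 95% intervals and were compared by two-sided Fisher's exact tests. Those tests compare the region sets of these 4 libraries, since regions are not biological replicates. P-values over the 19 gene lists were adjusted by Benjamini and Hochberg's method, as were those over chromosomes.

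Genes were taken from the RefSeq gene table of GRCm38.p6, with 21631 protein-coding genes. The planned measure was distance to a transcription start site. The table used gives the start and end of each gene but neither strand nor exons, so a peak counts as near a gene when it lies within 1 kb of either end, and a region is assigned to the protein-coding gene whose end is nearest, within 50 kb. Ends of genes that are not starts are thus included, and exons and introns are not told apart. Regions were placed near a gene end, inside a gene or between genes. The 19 lists of pathway, regulatory and cell type marker genes were fixed before the data were examined, and 371 of their 372 genes were matched, 2 of them by an older symbol. They cover propionate and branched-chain amino acid breakdown, fatty acid oxidation, fatty acid synthesis, cholesterol, glucose, the urea cycle, bile acid and xenobiotic metabolism, sex-biased liver genes, the circadian clock, the acute phase, stress responses, histone acylation, hepatocytes and 6 other classes of cells.

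The rule for named genes was also fixed before the data were examined. It took Pcca and Pccb, then the first 10 genes of each direction ordered by the authors' score or by peak length, then list genes with a PA-only or WT-only region, and then 5 genes with regions in all 4 libraries. With no score and nearly constant lengths, that order fell to position in the genome, so the genes it names are arbitrary ones on chromosome 1. A further order by place in the file was therefore added after the data were seen. It took regions from the upper 50% of both lists that lay over 1 kb from any peak of the other genotype. The test of how many genes of each list had a call in all 4 libraries, and the comparison of chromosomes, were added as well. Some genes that the rule or the lists take are not reported here.

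Alternatives were a reciprocal overlap of 50%, merging within 500 bp, autosomes only, a distance of 2 kb to a gene end, assignment within 10 kb, restricted against all other regions, and leaving out each library in turn. The planned stricter and equal-length lists by score could not be made. Their replacements by place in the file, the upper 50% of each list and the first 25683 lines of each, were added after seeing the data. In these cut lists a peak past the cut counts as not called. A region or gene restricted in them can thus have a peak of the other genotype further down its list. The planned searches for 20 sequence words and the GC content of regions need a genome sequence and were not run.

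The region calls and list tests were tested on simulated lists with 15328 sites. Of 228 planted PA-only regions 227 were found, as were all 100 planted WT-only regions. Of 28 planted list genes 26 were found near a gene end, 24 regions were assigned to that list, and 0 of the 18 other lists passed the adjusted threshold. No regions were planted at genes of the other lists, so that 0 was close to given. Every planted region was called in both libraries of its genotype. The simulation thus checks the computation and not the effects of missed calls or list length. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.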

Results

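Peaks of accessible chromatin were listed for 4 mouse liver libraries, 2 WT and 2 PA. The lists held 26280 peaks in WT 1, 25941 in WT 2, 25683 in PA 1 and 29765 in PA 2. The mean was 26110.5 ± 240 (SD, n = 2) in WT and 27724 ± 2886 (SD, n = 2) in PA, a difference smaller than the spread between the PA libraries. The peaks covered 10.5, 10.4, 10.3 and 11.9 Mb of chromosomes 1 to 19 and X. Merged over the libraries they made 38853 regions with a median length of 427 bp. Of these, 17581 (45.3%) were called in all 4 libraries and 10412 (26.8%) in 1 library. Regions in all 4 libraries lay within 1 kb of an end of a protein-coding gene in 44.3% of cases, against 10.7% of regions in 1 library. Depth per library is unknown.

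The study compared livers with wild-type and hypomorphic Pcca, and the mutated gene and its partner were looked at first. Neither locus had a region restricted to a genotype. Pcca (chromosome 14, 122484365 to 122889944, GRCm38) held 9 regions, of which 4 were called in all 4 libraries. The one highest in every list, at 122534040 to 122534470 inside the gene, stood 3.92% of the way down the WT 1 list, 2.96% down WT 2, 2.83% down PA 1 and 2.52% down PA 2. The other 3 began at 122548469, 122586912 and 122719619. The remaining 5 Pcca regions were called in 1 or 2 libraries. No library had a peak within 1 kb of either end of Pcca as annotated. The annotation used gives a single start and end per gene, so a transcript start inside that span would not count. The absence is therefore not read as a Pcca promoter without a call. Whether the region at 122534040 lies at such a start was not tested. Pccb, which encodes the beta subunit of propionyl-CoA carboxylase (chromosome 9, 100982032 to 101034940), had 1 region, at its upper end (101034421 to 101035127), called in all 4 libraries.

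The rest of the propionate and branched-chain amino acid breakdown list was as evenly called. A peak near a gene end was present in all 4 libraries for 24 of its 28 genes. Among them were Aldh6a1 and, acting downstream of or beside propionyl-CoA carboxylase, Mmut, Mcee, Mmaa and Mmab. Pcca, Bckdk and Acss1 had such a peak in no library, and Acss3 had one in WT 1 and PA 2. Of all regions assigned to these genes, 0 were restricted to a genotype. Among regions not restricted to a genotype, 52 belonged to the list. The share was 0 of 2083 restricted regions against 52 of the 36770 others (Fisher's exact test, two-sided, p = 0.116, adjusted p = 0.732). A count of 0 is already the lowest possible, so for a list of this size the test could not have shown a lack of restricted regions.

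Peaks near a gene end were called in all 4 libraries for most genes of several metabolic lists, and marker genes of minority cell types were mostly without such a call. Over all protein-coding genes, 8924 of 21631 (41.3%) had a peak near an end in all 4 libraries. The share was 90.0% (18 of 20) for cholesterol synthesis and uptake, with Sqle and Fdps, and 85.7% for propionate and branched-chain amino acid breakdown. It was 83.3% (15 of 18) for fatty acid and triglyceride synthesis, with Fasn and Scd1. It was 81.0% (17 of 21) for the integrated stress and unfolded protein responses, with Atf4 and Hspa5. For histone acylation writers, erasers and acyl-CoA suppliers it was 77.8% (21 of 27), with Kat8, the H4K16 acetyltransferase, Ep300, Sirt3 and Sirt5. The urea cycle, glutamine and glycine list reached 76.5% (13 of 17), with Cps1 and Otc, the glucose list 75.0% (15 of 20), with Pck1, G6pc and Fbp1, and the circadian clock list 66.7% (14 of 21), with Per1, Cry1 and Nr1d1. Each of these 8 lists was above the other genes (Fisher's exact test, two-sided, adjusted p from 3.67e-05 to 0.0362 over 19 lists, a test added after the data were seen).

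Shares for the acute phase list (56.5%, 13 of 23), fatty acid oxidation and ketogenesis (53.3%, 16 of 30), hepatocyte markers (50%, 10 of 20) and bile acid and xenobiotic metabolism (47.6%, 10 of 21) did not pass the adjusted threshold. In the same test 7 lists lay below the other genes (adjusted p from 0.00322 to 0.0429). They were liver endothelial markers (13.3%, Kdr and Tie1), bile duct cell markers (9.09%, Krt8), sex-biased liver genes (8.70%, C6 and Trim24), stellate cell markers (7.14%, Reln), lymphocyte markers (7.14%, Tcf7) and Kupffer cell markers (6.67%). The seventh was the neutrophil and erythroid list, with 0 of 13 genes called in all 4 libraries.

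**Figure D1:**
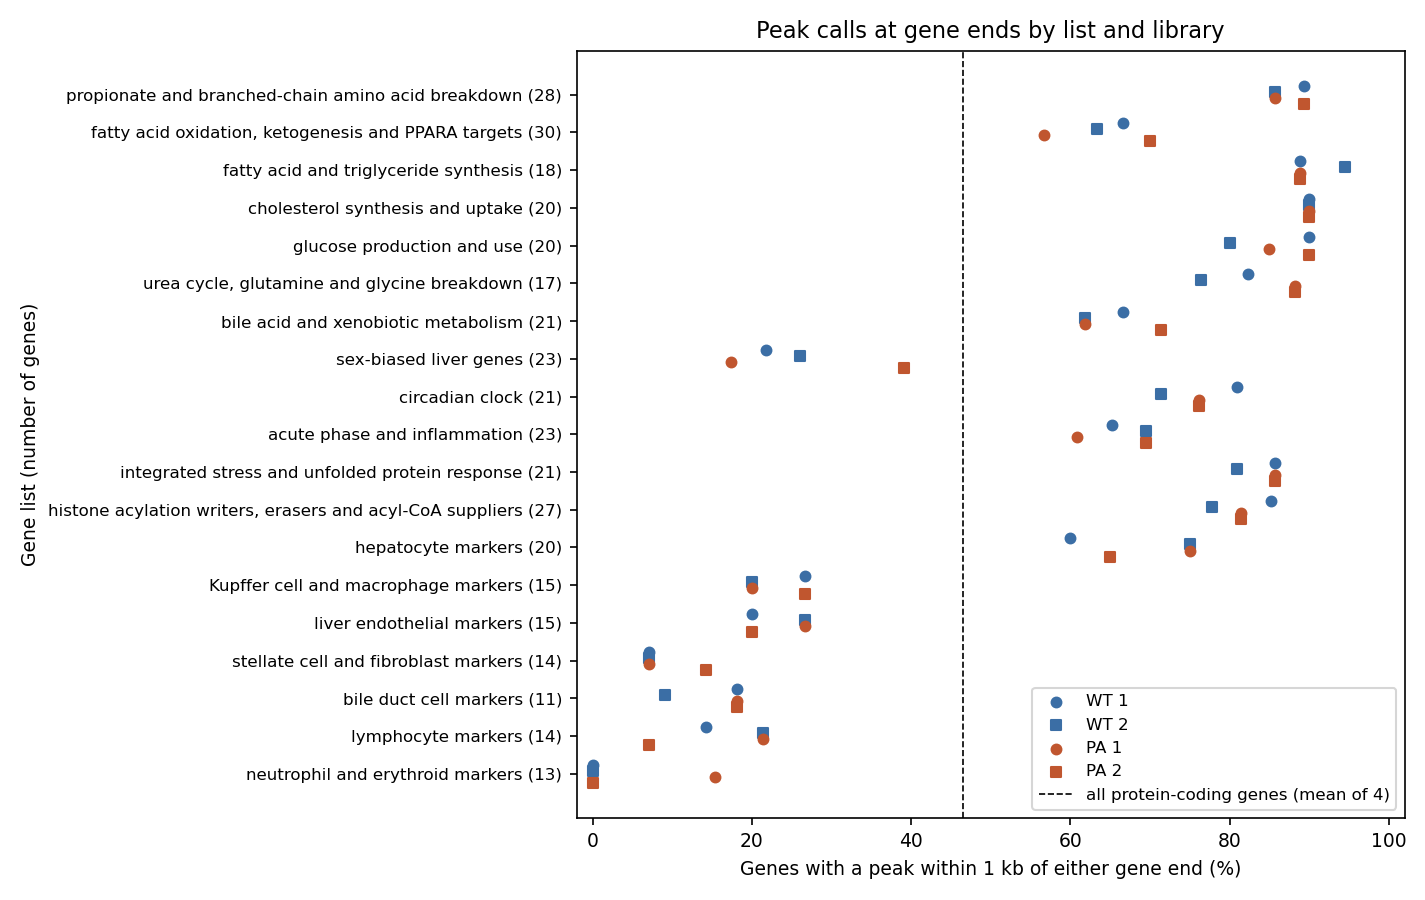
Percent of the genes of each list (vertical axis, number of genes in brackets) with a peak within 1 kb of either gene end (horizontal axis, %), for each library as a point, WT in blue and PA in orange. The dashed line is the mean over the libraries for all protein-coding genes, 46.5%, and the cholesterol list stands at 18 of 20 genes in every library.

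PA-only regions numbered 1315 and WT-only regions 768, and 28 and 12 of them were assigned to genes of the fixed lists. No list was over-represented among restricted regions against all other regions (Fisher's exact test, two-sided, smallest adjusted p = 0.732 over 19 lists), so the genes named next are single loci. A PA-only region overlapped an end of Arg1, which encodes arginase, the last enzyme of the urea cycle (chromosome 10, 24927308 to 24927777). It stood 31.6% of the way down the PA 1 list and 21.8% down the PA 2 list, and the nearest WT peak was 20618 bp away. A PA-only region lay 5925 bp from Pck1, the gene of cytosolic phosphoenolpyruvate carboxykinase, which acts in gluconeogenesis (chromosome 2, 173146713 to 173147148, between genes, 29.8% and 22.4% down the lists). Its nearest WT peak was 5500 bp away, and the ends of Pck1 itself had a call in all 4 libraries. A PA-only region lay inside Acaa1b, a peroxisomal thiolase of fatty acid oxidation (chromosome 9, 119155436 to 119155890), 1020 bp from a WT peak, while peaks near an end of Acaa1b were called in WT 1, WT 2 and PA 2 and not in PA 1. Another lay 389 bp from an end of Ahsg, which encodes the plasma protein fetuin-A (chromosome 16, 22899840 to 22900256), where WT 2 also had a peak at an end of the gene, 7744 bp from this region. One overlapped an end of Lcn2, an acute phase gene (chromosome 2, 32387725 to 32388173).

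WT-only regions of list genes included one over an end of Fabp1, the liver fatty acid binding protein (chromosome 6, 71199574 to 71200021), 30.9% and 26.9% of the way down the WT 1 and WT 2 lists and 9613 bp from the nearest PA peak. A WT-only region overlapped an end of Bcl6, a transcriptional repressor (chromosome 16, 23988669 to 23989085), 25.7% and 14.4% down the lists and 16184 bp from the nearest PA peak. Further WT-only regions lay inside Gys2, the liver glycogen synthase (chromosome 6, 142471049 to 142471451), inside Fdft1, squalene synthase (chromosome 14, 63164818 to 63165226), 12692 bp from Cebpa, a hepatocyte transcription factor (chromosome 7, 35134620 to 35135029), and 5631 bp from Hp, haptoglobin (chromosome 8, 109584803 to 109585258). At Slc38a2, a glutamine transporter gene, a PA-only and a WT-only region lay 196 bp apart, so that the genotypes differed there in the placing of neighbouring peaks.

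**Figure D2:**
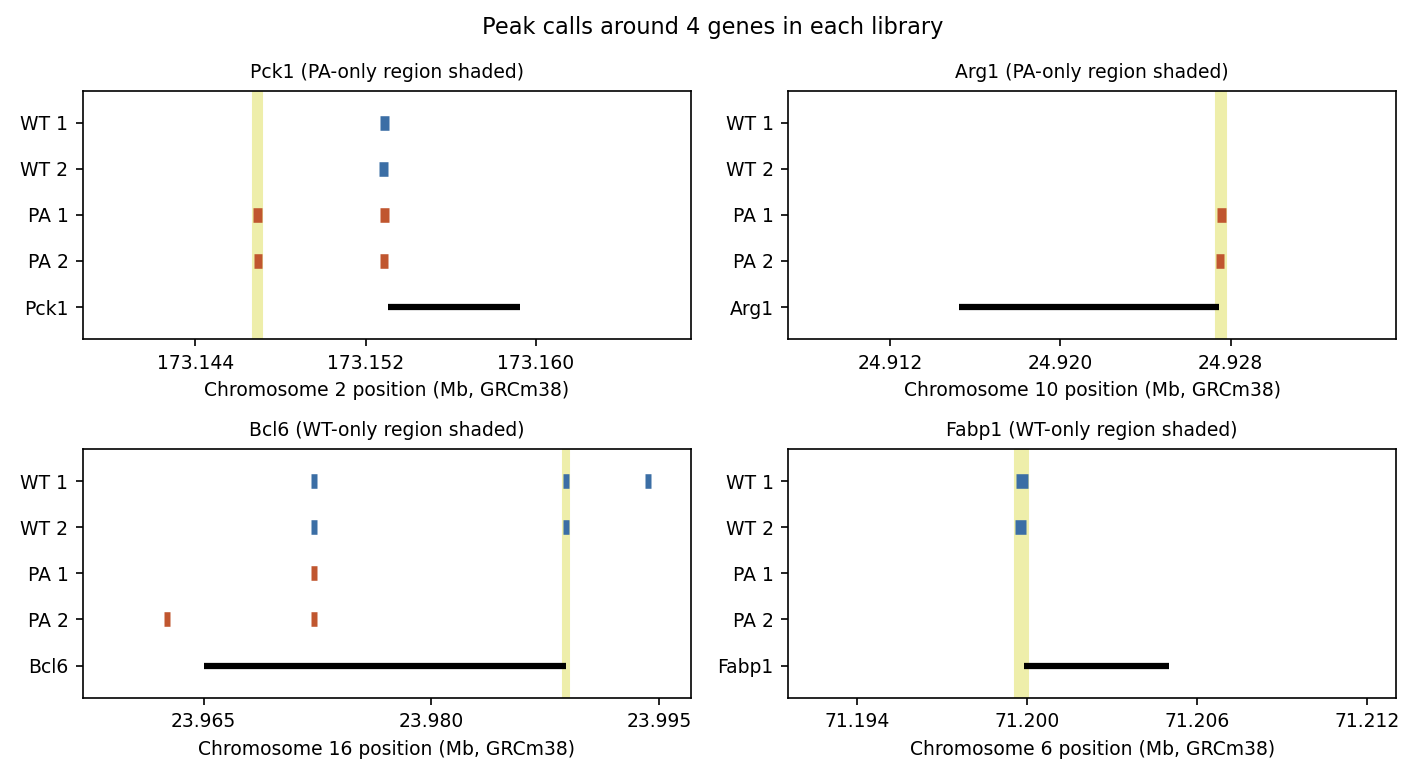
Peaks of each library (horizontal bars, WT in blue and PA in orange) along the chromosome (horizontal axis, Mb, GRCm38) around Pck1, Arg1, Bcl6 and Fabp1, with the gene as a black bar and the restricted region shaded. Peaks of the PA libraries alone fill the shaded region at Pck1 and Arg1, and peaks of the WT libraries alone at Bcl6 and Fabp1.

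Most restricted regions had at least 1 peak in the lower 50% of its list. Both peaks stood in the upper 50% of their lists for 101 PA-only (7.68%) and 130 WT-only regions (16.9%). Of the regions called in all 4 libraries, 54.4% had the peaks of all 4 in the upper 50%, a stricter condition. Leaving out those within 1 kb of a peak of the other genotype, 64 PA-only and 97 WT-only regions remained. The genes of those highest in the PA lists, an order chosen after the data were seen, were Zpr1, Errfi1 (a feedback inhibitor of the EGF receptor), Wbp2, Sdr42e1, Pon1 (paraoxonase, secreted by the liver), Bcl3, Mief2, Tedc2, N4bp2l1, Ahsg, Lasp1, Pck1, Zfp608, Aldh1l1 (a folate enzyme) and Arg1. Those highest in the WT lists were Id2 (an inhibitor of helix-loop-helix transcription factors), Sorbs3, Epb41l4b, Rgs3, Plxnb2, Myl6, Agpat2 (an enzyme of phosphatidic acid synthesis), Kdm6b (a histone H3K27 demethylase), Lekr1, Mettl7b, Tmem184b, Bcl6, Zbtb39, Dpp9 and Cdk15. The Id2 region (chromosome 12, 25098700 to 25099105) stood highest, 4.08% and 2.51% of the way down the WT 1 and WT 2 lists, and lay 2239 bp from the nearest PA peak. The Zpr1 region (chromosome 9, 46272818 to 46273284) overlapped an end of its gene, 13.9% and 10.2% down the PA 1 and PA 2 lists. At Lekr1 the calls near a gene end ran the other way, in both PA libraries and neither WT library, and the WT-only region lay 2496 bp from a PA peak.

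By the order fixed before the data were examined, which fell to genome position, the PA-only genes included Atp6v1h, Pcmtd1, Fam135a, Col19a1, Cnnm3, Rpl31, Il1r2, Cavin2 and Ankrd44, and the WT-only genes Sox17, Adhfe1, Sbspon, Tmem14a, Fam135a, Lmbrd1, Dst, Zap70, Lipt1 and Nab1. All lay on chromosome 1. At Fam135a the PA-only and the WT-only region were 142 bp apart. The corresponding genes with regions in all 4 libraries were Rp1, Mrpl15, Lypla1, Tcea1 and Atp6v1h, with the regions of Tcea1 and Atp6v1h at a gene end.

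Genotype was the split with the most restricted regions in the lists as deposited, but not with lists of equal length. The genotype split gave 2083 restricted regions, PA-only and WT-only together. WT 1 with PA 1 against WT 2 with PA 2 gave 1726 (517 and 1209), and WT 1 with PA 2 against WT 2 with PA 1 gave 1838 (1267 and 571). The product of the counts was 1.62 times (95% interval 1.41 to 1.85) and 1.40 times (1.22 to 1.59) that of those splits. With every list held to its first 25683 lines, the genotype split gave 1850, 840 PA-only and 1010 WT-only, the others 1522 and 1872, and the ratio was 1.48 (1.29 to 1.70) to the split of WT 1 with PA 1 and 0.970 (0.852 to 1.10) to that of WT 1 with PA 2. The excess of PA-only over WT-only regions, 547 in the lists as deposited, was -170 with equal lists. The cut takes the most lines from PA 2. Regions of both WT libraries whose only PA peak lay past the cut then count as WT-only. Cutting thus moves the difference towards WT by construction. In the upper 50% of the lists the genotype split gave 786 (494 PA-only and 292 WT-only) and the others 655 and 872. Of the regions restricted in the full lists, 101 PA-only and 130 WT-only had both peaks in that upper 50%. Many of the 494 and 292 therefore have a call of the other genotype past the cut. Leaving out a library loosens the condition on its genotype, so the counts rise by construction. PA-only and WT-only regions then numbered 2412 and 2464 without WT 1, 2674 and 3061 without WT 2, 5007 and 1280 without PA 1, and 4046 and 3013 without PA 2. Each time the difference moved towards the genotype that lost a library, which is an outcome of these lists and not of the condition alone. Of the PA-only regions 809 (61.5%) and of the WT-only regions 735 (95.7%) were restricted with equal lists as well.

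**Figure D3:**
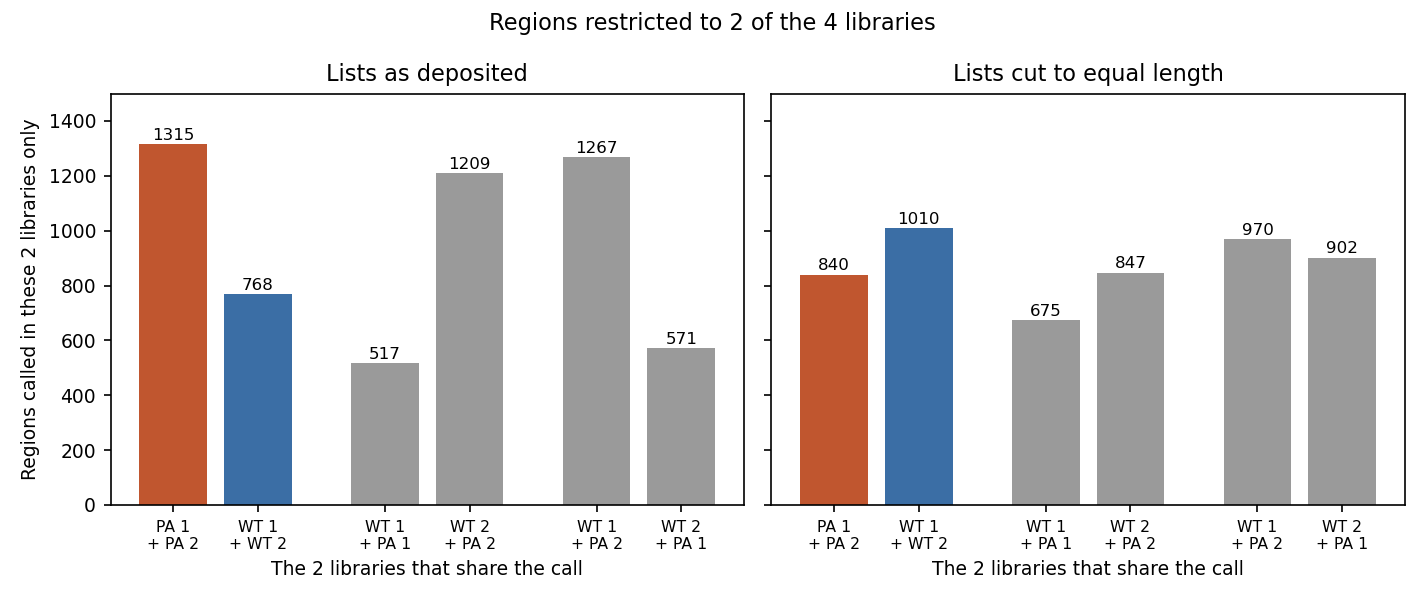
Number of regions (vertical axis) called in the named pair of libraries and in neither of the other libraries, with the lists as deposited on the left and at equal length on the right. PA pair in orange, WT pair in blue and mixed pairs in grey, showing 1315 PA-only regions as deposited and 840 at equal length.

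Libraries of one genotype were about as alike as libraries of different genotypes. The Jaccard index was 0.587 between the WT libraries and 0.544 between the PA libraries. Mixed pairs ranged from 0.525 (WT 1 and PA 1) to 0.589 (WT 2 and PA 2). The mean of the same-genotype pairs was 0.566 and that of the 4 mixed pairs 0.558 ± 0.0276 (SD), a difference of 0.00729 that lies within the spread of the mixed pairs. No test was run on it, since an exact permutation of the 4 libraries has only 3 splits.

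Where restricted regions lie relative to genes did not separate the genotypes in a stable way. A gene end lay within 1 kb of 177 of 1315 PA-only regions (13.5%, 11.66 to 15.42) and of 127 of 768 WT-only regions (16.5%, 13.98 to 19.36), an odds ratio of 0.785 (Fisher's exact test, two-sided, p = 0.0620). Most of both kinds lay inside genes (43.9% and 43.4%) or between them (42.7% and 40.1%). The other splits gave odds ratios of 1.58 (p = 0.00396) and 0.558 (p = 3.96e-05) by the same exact test, so the splits that mix genotypes lay further from 1. In every split the side holding PA 2 had the lower share. It was 10.1% for WT 2 with PA 2 against 15.1% for WT 1 with PA 1. For WT 1 with PA 2 it was 11.5%, against 18.9% for WT 2 with PA 1. Of its peaks, PA 2 had 31.1% near a gene end, WT 1 34.4%, WT 2 34.8% and PA 1 35.2%. The lower share thus went with PA 2 also where genotypes were mixed. By exact tests of the genotype split the odds ratio was 1.09 (p = 0.504) with equal lists, 2.49 (p = 1.56e-07) in the upper 50% of the lists, and 0.741 (p = 0.0121) at 2 kb. The cut lists admit regions with a call of the other genotype past the cut. The values for equal lists and the upper 50% thus concern other sets of regions. In the same exact test the odds ratio was 1.173 (p = 0.0497) without WT 1, 1.28 (p = 0.00106) without WT 2, 0.424 (p = 3.71e-22) without PA 1 and 0.829 (p = 0.00763) without PA 2. Such values concern other sets of regions. The genotype that lost a library takes in regions called in 1 library, which over all libraries lie near gene ends less often (10.7%). The other genotype takes in regions called in 3 libraries (17.5%). The shares among the regions taken in were not computed for each left-out library. Without PA 2 the odds ratio moved from 0.785 to 0.829, the opposite of what the pooled shares would give. What accounts for these values was not tested.

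Per gene, about the same share of genes had a peak near an end in each genotype, 46.3% ± 0.098 in WT and 46.7% ± 0.484 in PA (SD, n = 2). Among list genes, the calls found in both PA libraries and neither WT library were at Arg1, Cyp2a4 (a steroid hydroxylase higher in females), Lcn2 and Adgre1 (the macrophage marker F4/80). Those found in both WT libraries and neither PA library were at Fabp1, Bcl6, C1qb (a complement gene of macrophages) and Fcgr2b (an Fc receptor). Over all protein-coding genes 143 were called in both PA libraries alone and 103 in both WT libraries alone, 246 together. The other splits gave 168 (67 and 101) and 194 (103 and 91). With equal lists the genotype split gave 94 and 113, together 207, and the other splits gave 162 (86 and 76) and 222 (84 and 138). In the upper 50% of the lists the PA and WT counts were 168 and 44, together 212, and the other splits gave 156 (51 and 105) and 207 (59 and 148). Under the looser condition that a left-out library makes, the PA and WT counts were 343 and 279 without WT 1, 369 and 297 without WT 2, 337 and 228 without PA 1, and 391 and 384 without PA 2.

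Regions of list genes were too few to compare PA-only with WT-only regions list by list. They numbered 28 among PA-only and 12 among WT-only regions. Each was assigned to the nearest gene end within 50 kb. Some, as at Arg1 and Lcn2, overlapped that end, and others lay far from it. The distance was 49726 bp for Cux2, 47921 bp for Acaca, 44371 bp for Irs2, 39810 bp for Asns, 35386 bp for Pcx and 35082 bp for Nfil3. The Insig1 regions lay 11909 and 39415 bp away. The sex-biased list had the most, 5 PA-only (among them regions assigned to Hao2, Cyp3a44 and Cyp2a4) and 2 WT-only (assigned to Bcl6 and Cux2). The glucose list had 3 PA-only (Pck1, Irs2 and Pcx) and 1 WT-only region (Gys2), and the cholesterol list 2 (both assigned to Insig1) and 1 (Fdft1). The urea cycle list had 2 (Arg1 and Slc38a2) and 1 (Slc38a2), and the acute phase list 2 (Lcn2 and Ccl2) and 1 (Hp). Fatty acid oxidation had 1 PA-only (Acaa1b) and 1 WT-only region (Fabp1). Fatty acid synthesis had 2 PA-only regions (Me1 and Acaca), bile acid and xenobiotic metabolism 2 (Cyp7b1 and Abcc2), the stress list 2 (Asns and Vldlr) and the circadian list 1 (Nfil3), each with no WT-only region. Histone acylation genes had 0 restricted regions of 2083, against 49 among the other regions (Fisher's exact test, two-sided, p = 0.113, adjusted p = 0.732). Here too 0 is the lowest count possible, so the test could not have shown a lack of restricted regions.

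Markers of cell types were spread over both directions. Hepatocyte markers had 1 region each way (Ahsg and Cebpa), as did Kupffer cell markers (Adgre1 and C1qb), and endothelial markers had 2 each way (Bmp2 and Erg, and Cdh5 and Fcgr2b). Stellate cell markers had 1 PA-only region (Col1a2), 114 bp from a WT peak, bile duct markers 1 PA-only region (Cldn4), lymphocyte markers 1 WT-only region (Lck) and neutrophil and erythroid markers 0. Over the 19 lists 0 had an adjusted p under 0.05 by Fisher's exact test, and 0 an unadjusted p under 0.05 (smallest p = 0.369). The other splits had 0 adjusted, and 0 and 1 unadjusted. For 18 of the 19 lists, with 0 to 4 restricted regions each, no division of the regions between the genotypes could by itself have given an adjusted p under 0.05, the smallest possible being 0.349, so these counts of 0 say nothing about those lists. The exception was the sex-biased list with 7 regions (observed p = 1, Fisher's exact test). The regions assigned to Me1, Acaca, Pcx, Vldlr and Adgre1, and 1 of those assigned to Insig1, were not restricted with equal lists.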

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

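The versions by place in the file and the distance of over 1 kb to the other genotype's peaks were chosen after seeing the data. PA-only regions (1315) numbered 494 in the upper 50% of each list and 840 with equal lists, and WT-only regions (768) numbered 292 in the upper 50%. A peak past the cut counted as not called. Of the regions restricted in the full lists, 101 PA-only and 130 WT-only had both peaks in the upper 50%. Many of the 494 and 292 therefore have a call of the other genotype further down. The difference between PA-only and WT-only regions (547) was 202 in the upper 50% and turned to -170 with equal lists. PA 2 loses the most lines there, which by construction moves the difference towards WT. Leaving out each library in turn gave 2412 to 5007 PA-only and 1280 to 3061 WT-only regions and a difference from -387 to 3727, with -52 without WT 1 and -387 without WT 2. Leaving out a library asks for a call, or none, in 1 library of its genotype instead of 2. The counts therefore rise by construction, but how much each side rises depends on the lists. Regions rose most on the side of that genotype, whereas gene counts without WT 1 did not. Those were 343 for PA and 279 for WT, from 143 and 103. The sets differ from the main ones, and whether the turned sign speaks against the direction was not tested. Genes called near an end in both PA libraries alone (143) numbered 94 with equal lists and 337 to 391 with a library left out. Those called in both WT libraries alone (103) numbered 44 in the upper 50% and 228 to 384 with a library left out. The odds ratio of lying near a gene end (0.785) passed the threshold at 2 kb (0.741). It was 1.09 with equal lists and 2.49 in the upper 50%. Cutting the lists redefines the restricted sets, so these values do not test the same regions again. How far that accounts for them was not tested. With a library left out the odds ratio ranged from 0.424 (without PA 1) to 1.28 (without WT 2), with 1.173 without WT 1. The looser condition also admits regions of 1 library, over all libraries less often near gene ends (10.7%). Without PA 2 the odds ratio was 0.829, the opposite of the move that this pooled share would give. The share among the regions admitted was not computed for each left-out library, so their part in these values is open. Reciprocal overlap, merging within 500 bp, autosomes and the 1 kb distance kept the region counts within 1.5 times, with a difference from 522 to 551. The same held for the gene counts at 2 kb and on autosomes. The difference in Jaccard index (0.00729) was 0.00693 with reciprocal overlap and 0.00327 with equal lists, each within the spread of the mixed pairs. The count of lists that passed was 0 in all 7 alternatives, which shows no stability, since 18 lists could not pass by themselves at their main counts. No paired analysis was possible because, for region and gene calls, a call in both PA libraries and neither WT library is the same condition with or without pairing by replicate number. Values per library were not tested, paired or unpaired. Not run were the upper and equal lists by score, reciprocal overlap and merging for the gene counts, which use peaks of each library directly, and all settings of the sequence words, which need a genome. Depth is unknown, so how far it sets the length of each list is open.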

Other observations

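The comparison of chromosomes, the counts of genes with several regions, and the tests of list length (its odds ratios per chromosome included), of a genotype difference in accessibility and of neighbouring peaks were chosen after the results they bear on had been seen. The tests of the Pcca surroundings, of adjusted p per chromosome with equal lists and of single segments were set out before their results were seen.

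Several genes that hepatocytes express strongly had no peak at their ends in most or all libraries. Alb, the serum albumin gene, had one in PA 1 alone, and the nearest peak to an end was 10545 bp away in WT 1, 10474 bp in WT 2 and 3240 bp in PA 2. Foxa2, a hepatocyte transcription factor, had its nearest peak 12214, 12140, 12146 and 12184 bp from an end in WT 1, WT 2, PA 1 and PA 2. Asgr1, the asialoglycoprotein receptor gene, had 1 peak inside the gene in every library, 3345 to 3415 bp from an end. Ambp had a peak at an end in PA 1 and, in the others, a nearest peak 2701 or 2702 bp away. The absence of a call is therefore not read here as closed chromatin. Trf, Fga, Tdo2 and Apoh had a peak overlapping an end in all 4 libraries.

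Of the sex-biased liver genes, the 5 PA-only regions included 2 at Cyp2a4 and 1 at Cyp3a44, both genes higher in female than in male mouse liver, and at Hao2. The WT-only regions overlapped an end of Bcl6, higher in males, and lay 49726 bp from an end of Cux2, higher in females. All animals were female. None of the 5 PA-only regions stood in the upper 50% of both lists, whereas those at Bcl6 and Cux2 did. The list held 7 of 2083 restricted regions (0.336%) against 55 of 36770 others (0.150%), an odds ratio of 2.25 (Fisher's exact test, p = 0.0475, adjusted p = 0.732 over 19 lists), which does not pass the correction. Genes with 3 or more regions of one kind, singled out after seeing them, were Minpp1 and Zfp608 among PA-only regions and Dntt among WT-only regions. The mixed pairs of libraries gave 0, 1, 3 and 0 such genes.

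More PA-only than WT-only regions were found, and genotype gave the most restricted regions of the 3 splits, in the lists as deposited. With all lists at the length of the shortest, PA-only minus WT-only regions was -170, so the excess of PA-only regions may come from the longer PA 2 list. The order of lines this cut uses is undocumented, however. In the lists as deposited, without a cut, the side holding PA 2 was the larger in all 3 splits. The counts were 1315 against 768 for genotype, and 1209 against 517 and 1267 against 571 for the mixed splits. The larger side thus went with PA 2 also where genotypes were mixed. The cut also turns some regions with a PA 2 peak past it into WT-only regions. Neighbouring peaks of one wide open region, called at slightly different places, are argued against as the main source, since 8.26% of restricted regions (95% interval 7.11 to 9.52) lay within 1 kb of a peak of the other genotype, and 30.3% (24.4 to 36.7) of the 231 in the upper 50% of both lists, where neighbouring peaks thus stay open for a larger part. A difference in accessibility between the genotypes stays open. With equal lists the genotype split's product of counts was 0.970 times (0.852 to 1.10) that of WT 1 with PA 2 against WT 2 with PA 1 and 1.48 times (1.29 to 1.70) that of the other split, and 3 splits are too few to give a share under 0.05.

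WT-only regions were over-represented on chromosome 1 (10.03% of WT-only against 6.01% of PA-only regions, odds ratio 0.574, adjusted p = 0.01002) and on chromosome 4 (8.85% against 4.79%, odds ratio 0.518, adjusted p = 0.00691, Fisher's exact tests adjusted over chromosomes). No chromosome had an adjusted p under 0.05 in the other splits, the lowest being 0.104 and 0.299. A single segment that differs between the animals was looked for in 36 windows of 10 Mb. The smallest adjusted p was 0.228 (Fisher's exact tests, WT-only against all other regions), and 3 windows had an unadjusted p under 0.05. The highest window, 130 to 140 Mb on chromosome 4, held 32.0% of its chromosome's excess, and the window before it 15.5%. No window thus held most of the excess. The windows did not overlap, so a segment across a boundary would be split, and each held few WT-only regions. They therefore cannot decide on a single segment, of up to 10 Mb or longer, which stays open. With equal lists the odds ratio on chromosome 1 was 0.563 (95% interval 0.388 to 0.810, Fisher's exact test, adjusted p = 0.0240). It had been 0.574 (0.408 to 0.807). On chromosome 4 it was 0.581 (0.383 to 0.871, Fisher's exact test, adjusted p = 0.0595), where it had been 0.518 (0.357 to 0.751). The call of chromosome 4 thus ended with a change in odds ratio smaller than its interval. Cutting the lists redefines the restricted sets, however. It kept 735 of the 768 WT-only regions and 809 of the 1315 PA-only regions. It also admitted WT-only regions with a PA 2 peak past the cut. These odds ratios therefore cannot decide on the longer PA 2 list. A part played by list length, or a difference between the genotypes, stays open on chromosomes 1 and 4.

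A mutant line could carry a chromosome segment of another strain around the altered gene. Within 10 Mb of Pcca, 15 of 183 regions (8.20%) were restricted to a genotype, against 5.35% elsewhere, an odds ratio of 1.58 (95% interval 0.864 to 2.69, Fisher's exact test, two-sided, p = 0.0975). The other splits had odds ratios of 1.11 and 1.29 there. The number of regions is too small to tell such a segment from the rest of the genome, and a local effect of the mutation itself was not tested.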
